A study of Mus musculus with 6 samples.

How the data were processed

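RNA sequencing was used to measure gene expression in mouse thalamus, in 3 samples of a saline group and 3 samples of a group labelled Coll IV, with 1 library per sample. Per the labels, total RNA was extracted with TRIzol, the libraries were made with a commercial long RNA kit, and the molecule is given as polyA RNA. The series describes a comparison of a model group with a control group, and the Coll IV samples were taken as the model group because the other group received saline.

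The deposited gene table holds raw read counts per gene for each of the 6 libraries. Per the submitters' processing notes, HISAT2 2.1.0, a read aligner, and featureCounts 1.6.3, a read counter, were used. The notes list the builds GRCh38, GRCm38 and mm10 without saying what each was for, and the gene identifiers are those of mouse. The deposited FPKM table (fragments scaled by gene length and library size) was tested against the counts: dividing count by FPKM gave 1 constant per gene times 1 factor per library. That factor equalled the library size scaled by median-ratio factors, not the total count, and for saline replicate 3 it was 0.756 relative to saline replicate 1 where the totals gave 0.955. The strand setting, the read filters, the treatment of reads that map to several genes and the gene lengths behind the FPKM values are not given in the sources used here. Whether reads from overlapping genes on opposite strands were told apart is therefore unknown. Genes with near-identical copies, such as the globins and the H2 genes, have uncertain counts.

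The tables held 53465 genes. The library totals were 17603500, 19853672 and 16812880 counts for saline replicates 1 to 3 and 18058426, 18231304 and 17222627 counts for Coll IV replicates 1 to 3. A gene was tested where edgeR's filterByExpr kept it with the group factor (minimum count 10, minimum total 15), which left 19997 genes. Counts were put on a common library size as CPM, with library sizes scaled by TMM, edgeR's trimmed mean method, whose factors ran from 0.791 in saline replicate 3 to 1.18 in Coll IV replicate 1. Gene positions, lengths and GC contents came from GENCODE M21 on GRCm38, in which 53274 of the 53465 identifiers and 19959 of the 19997 tested genes were found.

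The comparison of Coll IV with saline was fitted with edgeR 4.0.16 (robust quasi-likelihood F test, group as the sole factor) in R 4.3.3. A gene was said to have risen or fallen at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are Coll IV over saline with their standard errors (SE), and CPM values are means with the SD over 3 libraries. Before the data were examined, 39 gene lists were fixed for cell types, neighbouring brain regions and processes of injury, bleeding and pain, and 38 of them were tested. Each list was tested with camera from limma 3.58.1, which compares a list's genes with all others, on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera was repeated with an estimated correlation and joined by fry, which asks whether a list's genes move 1 way on balance, all with Benjamini-Hochberg adjustment over the 38 lists. The list of sex-linked genes served to check the samples. Cacna1g was held by 2 lists, and every other gene by 1.

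The genes named in the text were chosen by a rule fixed before the data were examined. In each direction it took the 10 genes with the largest absolute log2 fold change and the 5 with the smallest adjusted p, among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes and pseudogenes. It added up to 4 members of each list with the smallest p, and not every gene that the rule took is printed. Members that passed with the adjustment over their list alone, and members of the region lists, are also named where they make up a count, and these were chosen after their values were seen.

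The groups share replicate numbers in the labels. The deviations of same-numbered samples from their group means correlated at 0.196, 0.154 and 0.123 across genes, and those of all other pairs at -0.119 to -0.0347. Deviations cancel out within a group, so the negative values follow in part from the positive ones and are not separate evidence. With 3 samples per group there are few ways to match them, so the labelled match could be the closest by chance. The numbers were taken as a possible pairing, from the data and not from a stated design. The fit with the replicate number as a block is given where it changes a call. The labels do not say whether the samples come from separate animals, so the p-values measure the spread between samples. No 2 libraries were copies of each other, with a chi-square per degree of freedom of at least 15.4 over all pairs. The common biological coefficient of variation was 16.3%.

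The fit was tested on simulated data with the real libraries' sizes and means, in 5 runs of 200 changed genes each. With gene-wise spreads and 19636 to 19716 genes per run, it recovered 22.1% of 1.5-fold, 66.6% of 2-fold and 95.2% of 4-fold changes, and 12.1% of the calls were false. With spreads on the fitted trend and 19568 to 19691 genes per run, these shares were 26.3%, 73.4% and 99.1%, with 5.01% of the calls false. In simulated lists of 16 genes, camera called 10 of 10 lists planted at 1.5-fold and 1 of 10 unchanged lists. These calls were at an unadjusted p under 0.05. The simulated genes varied independently, so the runs cannot show how often camera falsely calls lists of correlated genes.

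The alternatives were DESeq2 1.42.0, median-ratio factors, no composition factors, 2 other filters, limma-voom, limma on the FPKM values with pseudocounts of 1 and 0.1, the replicate block, other thresholds and leaving out each library. A correction for gene length and GC content, with and without the block, was added after the data were seen. Length was that of all exons of a gene merged, and GC content that of the longest transcript. Also added then were the omission of the 10 most abundant ribosomal RNA-like and similar genes, camera with the block and 2 further region lists. The networks of proteins, microRNAs and transcription factors that the series mentions were not built, because they need outside databases.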

Results

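Gene expression was measured in 6 libraries of mouse thalamus, a relay region of the brain, with 3 libraries from saline samples and 3 from samples labelled Coll IV, an abbreviation that the labels do not spell out. The libraries held 16812880 to 19853672 counts, and 28743 to 33145 genes had at least 1 count. Ribosomal RNA and similar transcripts (Gm42418, CT010467.1, Gm23935, mt-Rnr1 and mt-Rnr2) took 38.9%, 40.2% and 52.7% of the counts in saline replicates 1 to 3 and 31.4%, 41.0% and 38.9% in Coll IV replicates 1 to 3. Protein-coding genes took 39.7% of the counts in saline replicate 3 and 47.8% to 54.9% in the other libraries. The Y-linked gene Ddx3y was at 73.8 to 97.9 CPM and the X-inactivation transcript Xist at 0.424 to 0.940 CPM in all 6 libraries, and none of the 5 sex-linked genes passed the edgeR test. In a principal component analysis of log2 CPM, the first component held 36.6% of the variance and placed the saline libraries at -31.1 to -17.3 and the Coll IV libraries at 11.1 to 53.2, with Coll IV replicate 2 farthest out.

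The comparison of Coll IV with saline asked which genes differ between the model and the control, as the series describes. As lists, genes of thalamic, hypothalamic and habenular neurons were higher in Coll IV, together with lists of reactive astrocyte, matrix, myelin, chemokine and ion channel genes, while nuclear genes of oxidative phosphorylation were slightly lower. These are 9 list calls by camera with a preset correlation, and all were lost with an estimated correlation (camera adjusted p = 0.652 to 0.799) and by fry. The glutamate transporter gene Slc17a6, which loads synaptic vesicles in thalamic relay neurons, went from 53.9 ± 5.56 CPM in saline to 96.7 ± 19.7 CPM in Coll IV (SD, n = 3), and the vasopressin gene Avp from 1.23 ± 0.338 to 5.69 ± 2.09 CPM. The myosin light chain gene Myl4 went from 6.91 ± 0.742 to 1.06 ± 0.731 CPM, and Lamp5, a membrane protein gene of cortical neurons, from 52.6 ± 5.07 to 18.7 ± 6.29 CPM. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 192 of 19997 genes rose and 127 fell, with a smallest adjusted p of 0.0116. Of these 319 genes, 296 were protein coding, and the median absolute log2 fold change was 0.69. All 319 had every Coll IV library on the same side of every saline library, which follows in part from the test that chose them (chance gives 10% among genes not so chosen), and 35 that rose and 30 that fell had an absolute log2 fold change of at least 1.

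The counts were lower with any 1 library left out. With saline replicate 1 or saline replicate 3 left out, edgeR called 0 genes, with 3009 and 3211 genes at an unadjusted p under 0.05, while DESeq2 and limma-voom were run on all 6 libraries alone and called 419 and 168 genes higher and 381 and 130 lower. Without saline replicate 2, 17 rose and 24 fell, and without Coll IV replicate 1, 53 rose and 45 fell. Without Coll IV replicate 2, 110 rose and 100 fell, and without Coll IV replicate 3, 166 rose and 95 fell. Each of these fits had 1 library fewer, which by itself can lower the counts. With the replicate number as a block 406 rose and 329 fell, and 316 of the 319 genes were among them. Without composition factors the median log2 fold change of all genes shifted to 0.25 and the split was 1191 higher and 57 lower, against 192 and 127. Limma on log2(FPKM + 1) called 0 genes, with 3074 at an unadjusted p under 0.05, so no gene named here as risen or fallen passed in that test or without saline replicate 1 or 3.

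Avp and Lhx1 had the largest log2 fold changes of the named genes that rose. Avp (ENSMUSG00000037727, chromosome 2, 130580620 to 130582554, GRCm38) had a log2 fold change of 2.22 (SE 0.34, edgeR adjusted p = 0.0152). Hcrt (chromosome 11, 100761069 to 100762931), which encodes the orexin peptides of the lateral hypothalamus, rose by 1.73 (SE 0.39, edgeR adjusted p = 0.0492), from 0.683 ± 0.391 to 2.20 ± 0.332 CPM. Its adjusted p was 0.0591 after the length and GC correction. The transcription factor gene Lhx1 (chromosome 11, 84518284 to 84525535) rose by 2.02 (SE 0.41, edgeR adjusted p = 0.0395) from a low level of 0.519 ± 0.333 CPM. Dlk1 (chromosome 12, 109452823 to 109463336), an imprinted gene for a Notch-type ligand, rose by 1.85 (SE 0.27, edgeR adjusted p = 0.0152), from 2.72 ± 0.380 to 9.77 ± 3.67 CPM. The insulin receptor substrate gene Irs4 (chromosome X, 141710998 to 141725263) rose by 1.80 (edgeR adjusted p = 0.0329; 0.0521 with limma-voom). It overlaps Gm15295 on the opposite strand. Log2 fold changes of 1.53 to 1.64 were found for Abhd12b, Arhgap36, Glra1, Ret and Sytl4. Of these, Glra1 encodes a glycine receptor subunit and overlaps Gm12236 on the opposite strand, and Ret, a receptor for glial cell line-derived growth factors, had an adjusted p of 0.0416 in edgeR and 0.0897 in limma-voom.

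The orphan receptor gene Gpr101 (ENSMUSG00000036357, chromosome X, 57496668 to 57503757) had the smallest adjusted p of all genes. Its level was 5.69 ± 0.101 CPM in saline and 15.4 ± 1.84 CPM in Coll IV, a log2 fold change of 1.44 (SE 0.15, edgeR adjusted p = 0.0116). More abundant genes also rose. Gaa (chromosome 11, 119267887 to 119285454), the gene of the lysosomal enzyme that breaks down glycogen, went from 47.4 ± 5.17 to 87.3 ± 8.54 CPM (log2 fold change 0.88, edgeR adjusted p = 0.0132). Tmem130 rose by 0.88 on the log2 scale and Dner, a neuronal Notch ligand gene that overlaps Mir5126 on the opposite strand, by 0.78.

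Myl4 and AC152162.1 had the most negative log2 fold changes of the named genes that fell. Myl4 (ENSMUSG00000061086, chromosome 11, 104550663 to 104595753), an atrial myosin light chain that overlaps Gm22000 on the opposite strand, had a log2 fold change of -2.68 (SE 0.37, edgeR adjusted p = 0.0152). Xirp2, which encodes an actin-binding protein of striated muscle and overlaps Gm13601 on the opposite strand, had -2.22 (SE 0.41, edgeR adjusted p = 0.0312), and the cardiac myosin kinase gene Mylk3 had -2.08 (edgeR adjusted p = 0.0443; 0.0561 with limma-voom). Dkkl1 (chromosome 7, 45207519 to 45212147), a dickkopf-like gene, went from 4.55 ± 0.636 to 0.861 ± 0.390 CPM (log2 fold change -2.38, SE 0.33, edgeR adjusted p = 0.0132). The antisense RNA AC152162.1, which overlaps 1500015L24Rik on the opposite strand, had -2.41 and the serpin gene Serpinb8 -2.17. Trbc2, the constant segment of the T cell receptor beta chain, had -1.94, Asb11 -1.85 and Rad51ap2 -1.44. The edgeR adjusted p of Asb11 was 0.0416, and 0.0503 after the length and GC correction.

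Igfbp6 and Kcnt2 had the smallest p of the named genes that fell. Igfbp6 (ENSMUSG00000023046, chromosome 15, 102144362 to 102149511), an insulin-like growth factor binding protein, went from 10.9 ± 1.39 to 4.03 ± 0.275 CPM (log2 fold change -1.43, SE 0.17, edgeR adjusted p = 0.0132). The potassium channel genes Kcnt2 and Kcnh5 had log2 fold changes of -1.07 (SE 0.14) and -0.68 (SE 0.10). Kcnt2 overlaps 4930590L20Rik on the opposite strand. Golga7b had -0.77 (SE 0.11). Without composition factors Kcnh5 and Golga7b lost their calls, with edgeR adjusted p of 0.134 and 0.0624 and log2 fold changes of -0.43 and -0.52 while the median of all genes stood at 0.25.

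**Figure D1:**
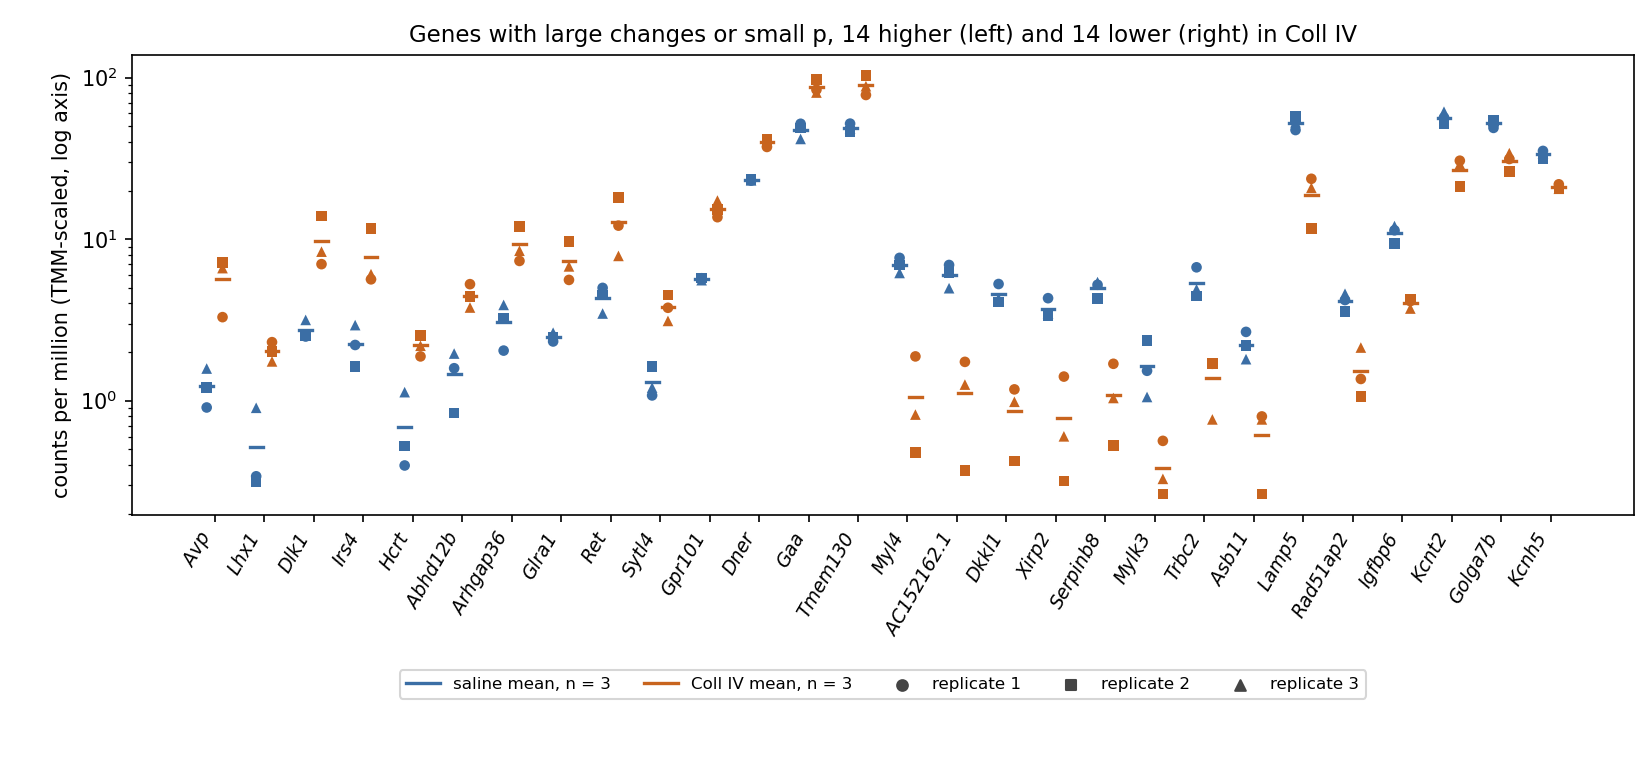
TMM-scaled CPM (log axis) of 14 genes that rose and 14 that fell under the naming rule, with 1 point per library, marker shape for the replicate number and a bar for the mean of 3 libraries per group. For Gpr101 the saline libraries lie at 5.57 to 5.76 CPM and the Coll IV libraries at 13.7 to 17.3 CPM.

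Of the 38 gene lists, 9 passed camera's adjusted p of 0.05 with the preset correlation, 8 upward and 1 downward. With an estimated correlation camera called 0 lists, with 2 lists at an unadjusted p under 0.05, and fry called 0 lists, with 7 at an unadjusted p under 0.05. Fry's mixed test asks whether a list's genes change in either direction and does not compare them with other genes. It called some lists that camera called and some that camera did not. Of the 9 lists, it called the thalamic, hypothalamus, habenula, matrix, ion channel and oxidative phosphorylation lists (mixed adjusted p = 0.00241 to 0.0361). It did not call the reactive astrocyte, myelin and cytokine lists (mixed adjusted p = 0.268 to 0.357). Its smallest adjusted p was 9.04e-05, for the GABAergic list. Camera with the replicate block called 13 lists and fry with the block 0. For the lists that did not pass, the range of the median with each library left out in turn follows the median. In edgeR 0 genes passed in 26 of the lists, where 52 of 318 genes had an unadjusted p under 0.05. The share was similar over all 19997 tested genes, of which 1770 were higher and 1728 lower at that p. DESeq2 called 35 of the 119 named genes that edgeR did not call and that it tested.

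Thalamic neuron genes rose as a list (camera adjusted p = 1.98e-07; adjusted p = 0.652 with an estimated correlation). Of 16 thalamic glutamatergic genes tested, 4 rose, 12 rose adjusted over the list alone, 15 had a positive log2 fold change, and the median was 0.72. The 4 were Slc17a6 (log2 fold change 0.84, SE 0.14), Prkcd (0.98, SE 0.13), a kinase gene of relay neurons, Cacna1g (0.54, SE 0.11), the T-type calcium channel behind thalamic burst firing, and the transcription factor gene Lhx9 (1.00, SE 0.21). Tcf7l2, Calb2, Ntng1 and Synpo2 had log2 fold changes of 0.91, 0.86, 0.69 and 0.82. With the replicate block 6 genes of the list rose, Synpo2 among them (edgeR adjusted p = 0.0400). The edgeR adjusted p of Cacna1g was 0.0352, and 0.0716 after the length and GC correction, and that of Lhx9 was 0.0416, and 0.0542 with limma-voom.

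Lists of the hypothalamus and the habenula, regions next to the thalamus, had the same direction. The hypothalamus list rose (camera adjusted p = 2.54e-05; adjusted p = 0.652 with an estimated correlation), with 2 of 8 genes risen (Avp and Hcrt), 4 risen adjusted over the list alone, all 8 positive and a median of 1.20. Oxt, the oxytocin gene, had a log2 fold change of 2.03 (SE 0.49) and Trh, the thyrotropin-releasing hormone gene, 0.81 (SE 0.20), which passed with the replicate block (edgeR adjusted p = 0.0230). All 8 of these genes were also detected in the saline libraries. The habenula list rose (camera adjusted p = 0.00249; adjusted p = 0.652 with an estimated correlation), with 0 of 7 genes risen in edgeR, 4 risen adjusted over the list alone and all 7 positive, at a median of 0.82. Its leading genes were Chrnb3 (1.49, SE 0.35), Pou4f1 (1.19), Gpr151 (0.85) and Tac2 (0.82), and Chrnb3 passed with the replicate block (edgeR adjusted p = 0.0337).

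The hippocampus and cortex list did not pass. In the hippocampus and cortex list, 1 of 12 genes rose, 1 fell, and 1 rose and 1 fell adjusted over the list alone, with a median of -0.66 (range -0.91 to -0.37) and a camera adjusted p of 0.266. Lamp5 fell (log2 fold change -1.49, SE 0.25, edgeR adjusted p = 0.0437), but had adjusted p of 0.0613 with the replicate block and 0.0520 after the length and GC correction. Prox1, a transcription factor gene of dentate granule cells, rose by 0.93 (SE 0.15, edgeR adjusted p = 0.0185). Fezf2 (-1.30), Neurod6 (-1.09), Slc17a7 (-1.01) and Tbr1 (-0.87), genes of cortical projection neurons, did not pass but had all Coll IV libraries under all saline libraries. Of the 12 genes, 6 were apart in this direction and 2 in the other, and the cortex genes Cux2 (-0.06) and Nrn1 (-0.44) overlapped. For 1 gene with no group difference, chance gives 10% for both directions together. The share over all tested genes was not computed, so these counts are not weighed against it. The hippocampal genes C1ql2, Fibcd1 and Wfs1 had 0.64, 0.50 and 0.47. In the striatum list 0 of 8 genes passed in edgeR or adjusted over the list alone (median -0.31, range -0.68 to 0.04, camera adjusted p = 0.180), with Ppp1r1b at -0.97, Drd1 at -0.56, Foxp1 at -0.34 and Rgs9 at -0.28. Without composition factors both lists passed camera downward, with medians of -0.39 and -0.05 against 0.25 for all genes and adjusted p of 0.00637 and 0.00787, and without Coll IV replicate 1 the striatum list passed too (camera adjusted p = 0.00423). Coll IV replicate 2 was lowest for 7 of the 12 hippocampus and cortex genes, and its mean log2 CPM over the striatum genes stood -1.30 from the mean of the 6 libraries, where the other libraries lay at -0.08 to 0.60. Without Coll IV replicate 2 the striatum median was 0.04 with camera's direction upward, and the hippocampus and cortex median was -0.37 (camera adjusted p = 0.0806).

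Inhibitory neuron genes did not pass as a list. Of 13 GABAergic genes, 4 rose, and adjusted over the list alone 4 rose and 2 fell (median 0.10, range 0.01 to 0.25, camera adjusted p = 0.371). The GABA-synthesising enzyme genes Gad1 and Gad2 rose by 0.51 and 0.56, the vesicular GABA transporter gene Slc32a1 by 0.84 and Ecel1 by 1.11, while the interneuron peptide genes Vip and Npy had -1.05 and -1.04, of which Vip fell with the replicate block (edgeR adjusted p = 0.0307). After the length and GC correction Gad1 and Slc32a1 had edgeR adjusted p of 0.0542 and 0.0502. Of 18 general neuron and synapse genes, 1 rose, and adjusted over the list alone 4 rose and 1 fell (median 0.00, range -0.06 to 0.10, camera adjusted p = 0.543). Nefh (0.67), Nefm (0.39) and Syn1 (0.45) were among the leading genes, Snap25 had -0.32, and Nefh passed with the replicate block (edgeR adjusted p = 0.0167).

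Ion channel genes rose as a list (camera adjusted p = 0.00249; adjusted p = 0.652 with an estimated correlation). Of 20 voltage-gated and pacemaker channel genes, 3 rose and 5 rose adjusted over the list alone, with 16 positive and a median of 0.24. The 3 were the pacemaker channel gene Hcn4 (log2 fold change 1.16, SE 0.23), Kcnc1 (0.75, SE 0.11) and Cacna1g, and Kcna2 (0.41) and Cacna1a (0.31) followed. Hcn4 had an edgeR adjusted p of 0.0541 after the length and GC correction. Of 18 glutamate receptor genes 0 passed in edgeR, and 2 rose adjusted over the list alone, among them Grin2d at 0.86 (median -0.00, range -0.10 to 0.05, camera upward, adjusted p = 0.980). Gria2 and Gria3 had -0.48 and -0.45, and with the replicate block Grin2d (edgeR adjusted p = 0.0335) rose and Gria2 (edgeR adjusted p = 0.0334) fell. Of 16 GABA and glycine receptor genes, the chloride transporter gene Slc12a5 rose (0.49; edgeR adjusted p = 0.0286, and 0.0551 after the length and GC correction), and 2 rose adjusted over the list alone (median -0.07, range -0.15 to -0.01, camera adjusted p = 0.865). Glra2 (0.62; edgeR adjusted p = 0.0472 with the replicate block), Gabra3 (-0.34) and Gabbr2 (0.30) came next.

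Of 20 genes of pain neuropeptides and purinergic signalling, 0 passed in edgeR and 1 rose adjusted over the list alone, the substance P receptor gene Tacr1 (log2 fold change 1.06). The list had a median of 0.19 (range 0.09 to 0.20) and a camera adjusted p of 0.449. The galanin gene Gal had 1.29, the opioid receptor gene Oprd1 -0.52 and the cholecystokinin receptor gene Cckbr -1.0, which fell with the replicate block (edgeR adjusted p = 0.0424). Of 14 immediate early genes, 0 passed in edgeR and Jun (0.64) rose adjusted over the list alone (median 0.04, range -0.11 to 0.50, camera adjusted p = 0.710), with Atf3 at 1.44, Nr4a1 at -0.92 and Junb at 0.36. The list's median was 0.50 without saline replicate 3 and 0.26 without Coll IV replicate 2. With the replicate block Jun rose (edgeR adjusted p = 0.0236) and Nr4a1 fell (edgeR adjusted p = 0.0425).

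Reactive astrocyte genes rose as a list (camera adjusted p = 0.00108; adjusted p = 0.799 with an estimated correlation). None of the 19 genes passed in edgeR, 2 rose adjusted over the list alone, and all 19 were positive with a median of 0.76. With the replicate block 5 of them rose. The pentraxin gene Ptx3 (log2 fold change 1.12), Tm4sf1 (0.79), S1pr3 (1.12) and the hyaluronan receptor gene Cd44 (1.32) had the smallest p, and Ptx3 and Cd44 passed with the replicate block (edgeR adjusted p = 0.0350 and 0.00457). Gfap, the astrocyte filament gene, was at 343, 281 and 157 CPM in saline and 471, 650 and 203 CPM in Coll IV. Coll IV replicate 2 was highest for 13 of the 19 genes, and without it the median was 0.46 (camera adjusted p = 0.0216). Of 12 homeostatic astrocyte genes 0 passed in edgeR, and adjusted over the list alone 2 rose and 3 fell (median 0.01, range -0.04 to 0.06, camera downward, adjusted p = 0.920). The glutamate transporter genes Slc1a3 and Slc1a2 had -0.36 and -0.40, the potassium channel gene Kcnj10 0.58 and Slc7a10 0.51.

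Myelin genes rose as a list (camera adjusted p = 0.00447; adjusted p = 0.799 with an estimated correlation). Of 12 oligodendrocyte genes, 1 rose, 3 rose adjusted over the list alone and all were positive, with a median of 0.31. Myrf, the transcription factor that drives myelination, rose by 0.94 (SE 0.17), and Mag and Opalin had 0.57 and 0.73, of which Mag passed with the replicate block (edgeR adjusted p = 0.0254). Without Coll IV replicate 2 the median was 0.23 (camera adjusted p = 0.0806). Of 10 precursor genes 0 passed in edgeR and 2 rose adjusted over the list alone (median 0.29, range 0.25 to 0.39, camera adjusted p = 0.0659), with Lhfpl3 at 0.52, Sox10 at 0.77, Olig1 at 0.58 and Enpp6 at 0.54. Lhfpl3 passed with the replicate block (edgeR adjusted p = 0.0459) and after the length and GC correction (edgeR adjusted p = 0.0494). The precursor list passed without saline replicate 1 (camera adjusted p = 0.0487) and without Coll IV replicate 3 (camera adjusted p = 0.0204).

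Matrix and scar genes rose as a list (camera adjusted p = 0.00249; adjusted p = 0.652 with an estimated correlation). Of 16 genes, 2 rose, 5 rose adjusted over the list alone and 14 were positive, with a median of 0.38. Sparc, a matrix-binding glycoprotein gene, rose by 0.96 (SE 0.16), and the metalloproteinase inhibitor gene Timp2 rose by 0.58 (SE 0.10), from 33.3 ± 2.73 to 49.8 ± 1.88 CPM. Tnc (1.38), Mmp12 (2.36) and Tgfbi (1.31) passed adjusted over the list alone, and all 3 also passed with the replicate block (edgeR adjusted p = 0.0434, 0.0219 and 0.0309), where 6 genes of the list rose and 1 fell.

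Cytokine and chemokine genes rose as a list (camera adjusted p = 0.00906; adjusted p = 0.799 with an estimated correlation). None of 16 genes passed in edgeR, 2 rose adjusted over the list alone and 13 were positive, with a median of 1.12. The chemokine genes Ccl4 (log2 fold change 2.73), Ccl7 (1.48), Ccl12 (1.25) and Ccl5 (1.06) had the smallest p, at means of 0.204, 1.35, 8.64 and 0.709 CPM in saline, and Ccl4 and Ccl7 passed with the replicate block (edgeR adjusted p = 0.0236 and 0.0382), where 4 genes of the list rose. Coll IV replicate 3 was highest for 11 of the 16 genes. The list's call ended without it (camera adjusted p = 0.0900, median 0.58) and without saline replicate 1 (camera adjusted p = 0.137).

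Genes of resident and infiltrating immune cells did not pass as lists. Homeostatic microglia genes had a median of -0.22 (range -0.40 to -0.08, 0 of 12 passed, camera adjusted p = 0.310), with P2ry12 at -0.66, Siglech at -0.85, Sall1 at -0.52 and Tmem119 at -0.34. Activated microglia and phagocyte genes had a median of 0.15 (range -0.06 to 0.36, 0 of 18, camera adjusted p = 0.494), with Lyz2 at 0.78, Clec7a at 0.86, Lgals3 at 1.68 and Cd68 at -0.58. Monocyte and border macrophage genes had a median of 0.69 (range 0.07 to 1.06, 0 of 11, camera adjusted p = 0.420), with Plac8 at 1.66, Ccr2 at 1.25, Cd163 at -0.67 and Ly6c2 at 1.91. Without Coll IV replicate 2 the monocyte median was 0.07 and the phagocyte median -0.06, with camera's direction downward for both (adjusted p = 0.886 and 0.677), and with the replicate block 2 monocyte genes rose. None of these 3 lists had a gene past the threshold adjusted over the list alone. The microglia list passed downward without saline replicate 2 (camera adjusted p = 7.02e-04), and the phagocyte list passed upward without Coll IV replicate 3 (camera adjusted p = 0.00783). All 7 neutrophil genes were positive (0 passed in edgeR or adjusted over the list alone, median 0.75, range 0.40 to 1.24, camera adjusted p = 0.0688, and 0.00117 with the replicate block). Their adjusted p was 0.799 by camera with an estimated correlation and 0.312 by fry with the replicate block. Csf3r had 0.75, Mmp8 0.98, and the alarmin genes S100a8 and S100a9 had 1.67 and 1.47, with edgeR adjusted p of 0.0323 and 0.0309 with the replicate block. The neutrophil list also passed without saline replicate 2 (camera adjusted p = 0.00764) and without Coll IV replicate 1 (camera adjusted p = 0.00284), while without Coll IV replicate 2 its median was 0.40 (camera adjusted p = 0.331).

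Of 4 T and NK cell genes, Trbc2 fell, also adjusted over the list alone, and Cd4, Gzma and Lck had -0.45, 0.57 and 0.05 (median -0.20, range -0.46 to 0.41, camera adjusted p = 0.371). The T cell receptor complex genes Cd3e, Cd3d and Cd3g were too low to test, at 19, 23 and 30 counts over all 6 libraries. Of 2 B cell genes 0 passed in edgeR, and adjusted over the list alone Pax5 rose (1.98) and Ighm fell (-1.11), with a median of 0.44 (range -0.04 to 1.02) where camera's direction was downward (adjusted p = 0.980). With the replicate block both passed (edgeR adjusted p = 0.0414 for Pax5 and 0.0167 for Ighm). Complement genes had a median of 0.16 (range -0.08 to 0.31, 0 of 14, camera adjusted p = 0.484), with C4b at 0.79, Itgb2 at 0.74, Itgam at 0.51 and C5ar1 at 0.59. Interferon response genes had a median of 0.17 (range -0.08 to 1.01, 0 of 20, camera adjusted p = 0.326, and 0.0160 with the replicate block), with Oasl2 at 0.63, Stat2 at 0.18, Rsad2 at 0.78 and Rtp4 at 0.40. The interferon list had an adjusted p of 0.960 by camera with an estimated correlation and 0.668 by fry with the replicate block. Rsad2 passed with the replicate block (edgeR adjusted p = 0.0462), and Ifit1 was at 41.8 CPM in saline replicate 3 and 46.9 CPM in Coll IV replicate 3 against 6.52 to 19.2 CPM elsewhere. Antigen presentation genes, whose H2 members share reads, had a median of 0.31 (range -0.12 to 0.67, 0 of 14, camera adjusted p = 0.279), with Ciita at 0.57, Tap2 at 0.58, H2-DMa at -0.36 and H2-Eb1 at 0.72. The complement, interferon and antigen presentation lists had 0 genes past the threshold adjusted over the list alone. Without saline replicate 3 the interferon and antigen presentation lists passed (camera adjusted p = 2.46e-04 and 0.0101), as did the interferon list without Coll IV replicate 1 (camera adjusted p = 0.00720) and the complement list without Coll IV replicate 3 (camera adjusted p = 0.0301). Without Coll IV replicate 2 the medians of the complement, interferon and antigen presentation lists were -0.08, 0.04 and -0.12, and without saline replicate 1 the interferon and antigen presentation medians were -0.03 and 0.06, with camera's direction downward for both.

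Vessel genes did not pass. Endothelial genes had a median of 0.08 (range -0.05 to 0.17, 0 of 12, camera adjusted p = 0.832), with Slco1a4 at -0.46, Tjp1 at 0.18, Flt1 at 0.28 and Cdh5 at 0.28. Mural cell and fibroblast genes had 0.23 (range 0.07 to 0.36, 0 of 12, camera adjusted p = 0.421), with Myh11 at 0.39, Dcn at 0.29, Tagln at 0.78 and Acta2 at 0.41. All 5 erythroid genes were positive (0 passed, median 0.68, range 0.38 to 1.27, camera adjusted p = 0.0595, and 9.41e-04 with the replicate block), with Hba-a2 at 0.82, Alas2 at 0.41, Hba-a1 at 0.99 and Hbb-bs at 0.68. As a list they had an adjusted p of 0.799 by camera with an estimated correlation and 0.262 by fry with the replicate block. The globin genes Hbb-bs, Hba-a1 and Hba-a2 passed with the replicate block (edgeR adjusted p = 0.0148, 0.0426 and 0.0337). Hbb-bs was at 204, 622 and 254 CPM in saline and 350, 836 and 545 CPM in Coll IV, highest in replicate 2 of both groups. These 3 lists had 0 genes past the threshold adjusted over the list alone. The erythroid list passed without saline replicate 2 or Coll IV replicate 1 (camera adjusted p = 0.00143 and 0.00426), and the mural cell and fibroblast list without Coll IV replicate 3 (camera adjusted p = 0.0162). Without Coll IV replicate 2 the erythroid median was 0.38 (camera adjusted p = 0.223) and the mural cell and fibroblast median 0.07 with camera's direction downward.

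Of 14 heme and iron genes, the heme-hemopexin receptor gene Lrp1 rose (0.48; edgeR adjusted p = 0.0460, and 0.0956 after the length and GC correction), and adjusted over the list alone 3 rose and 1 fell (median 0.18, range 0.01 to 0.35, camera adjusted p = 0.259). The zinc and iron transporter gene Slc39a14 had 0.64, the transferrin gene Trf 1.40 and the transferrin receptor gene Tfrc -0.56. With the replicate block Slc39a14 rose (edgeR adjusted p = 0.0309) and Tfrc fell (edgeR adjusted p = 0.0149). The list passed without Coll IV replicate 3 (camera adjusted p = 0.0441), and its median was 0.01 without Coll IV replicate 2. Hmox1, which breaks down heme, was at 39.7 CPM in Coll IV replicate 2 and 2.41 to 13.7 CPM in the other libraries, and rose with the replicate block (edgeR adjusted p = 0.00457). Ferroptosis and oxidative stress genes had a median of 0.13 (range -0.04 to 0.28, 0 of 14, also adjusted over the list alone, camera adjusted p = 0.710), with Gpx4 at -0.33, Srxn1 at 0.31, Gclc at -0.17 and Gclm at 0.20.

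Of 8 choroid plexus genes, the transthyretin gene Ttr rose (0.55, SE 0.11, edgeR adjusted p = 0.0413), also adjusted over the list alone, with Aqp1 at -0.70, Clic6 at 0.38 and Otx2 at 0.52 (median 0.20, range 0.10 to 0.33, camera adjusted p = 0.136). All 8 ependymal genes were positive, 0 passed in edgeR and Fam183b (0.92) rose adjusted over the list alone (median 0.49, range 0.12 to 0.76, camera adjusted p = 0.0650, and 0.0385 with the replicate block), with Tekt1 at 0.68, Ccdc153 at 0.47 and Dynlrb2 at 0.56. Camera with an estimated correlation gave this list an adjusted p of 0.799, and fry with the replicate block 0.527. The ependymal list also passed without saline replicate 3 (camera adjusted p = 0.0469) and without Coll IV replicate 3 (camera adjusted p = 0.00116), while without Coll IV replicate 2 its median was 0.12 (camera adjusted p = 0.405). Cell cycle genes had a median of -0.08 (range -0.22 to 0.24, 0 of 7, also adjusted over the list alone, camera adjusted p = 0.441), with Ccna2 at -0.28, Ccnb2 at 0.47 and Cenpe at -0.18. Ccnb1 had -2.85 with 7.0 CPM in saline replicate 3, and fell with the replicate block (edgeR adjusted p = 0.0284). Cell death and p53 genes had a median of -0.01 (range -0.06 to 0.21, 0 of 11, also adjusted over the list alone, camera upward, adjusted p = 0.980), with Gadd45a at 0.42, Bbc3 at -0.35, Mlkl at 0.57 and Casp8 at 0.29.

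Oxidative phosphorylation genes of the nucleus fell as a list (camera adjusted p = 0.00383; adjusted p = 0.725 with an estimated correlation). None of 16 genes passed in edgeR, 5 fell adjusted over the list alone and 15 were negative, with a median of -0.13. The succinate dehydrogenase gene Sdhb had a log2 fold change of -0.46 (SE 0.10) and fell with the replicate block (edgeR adjusted p = 0.0471), and Uqcrc2, Cox4i1, Ndufa4 and Cox6c had -0.38, -0.34, -0.30 and -0.29. Without composition factors the list's median was 0.12, under the median of all genes at 0.25, and its camera adjusted p was 0.177. Genes encoded in the mitochondrial genome had a median of -0.17 (range -0.24 to -0.12, 0 of 11, also adjusted over the list alone, camera adjusted p = 0.180), with mt-Cytb at -0.31, mt-Atp6 at -0.37, mt-Nd6 at -0.25 and mt-Co3 at 0.26. After the length and GC correction their median was -0.04 (camera adjusted p = 0.945).

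**Figure D2:**
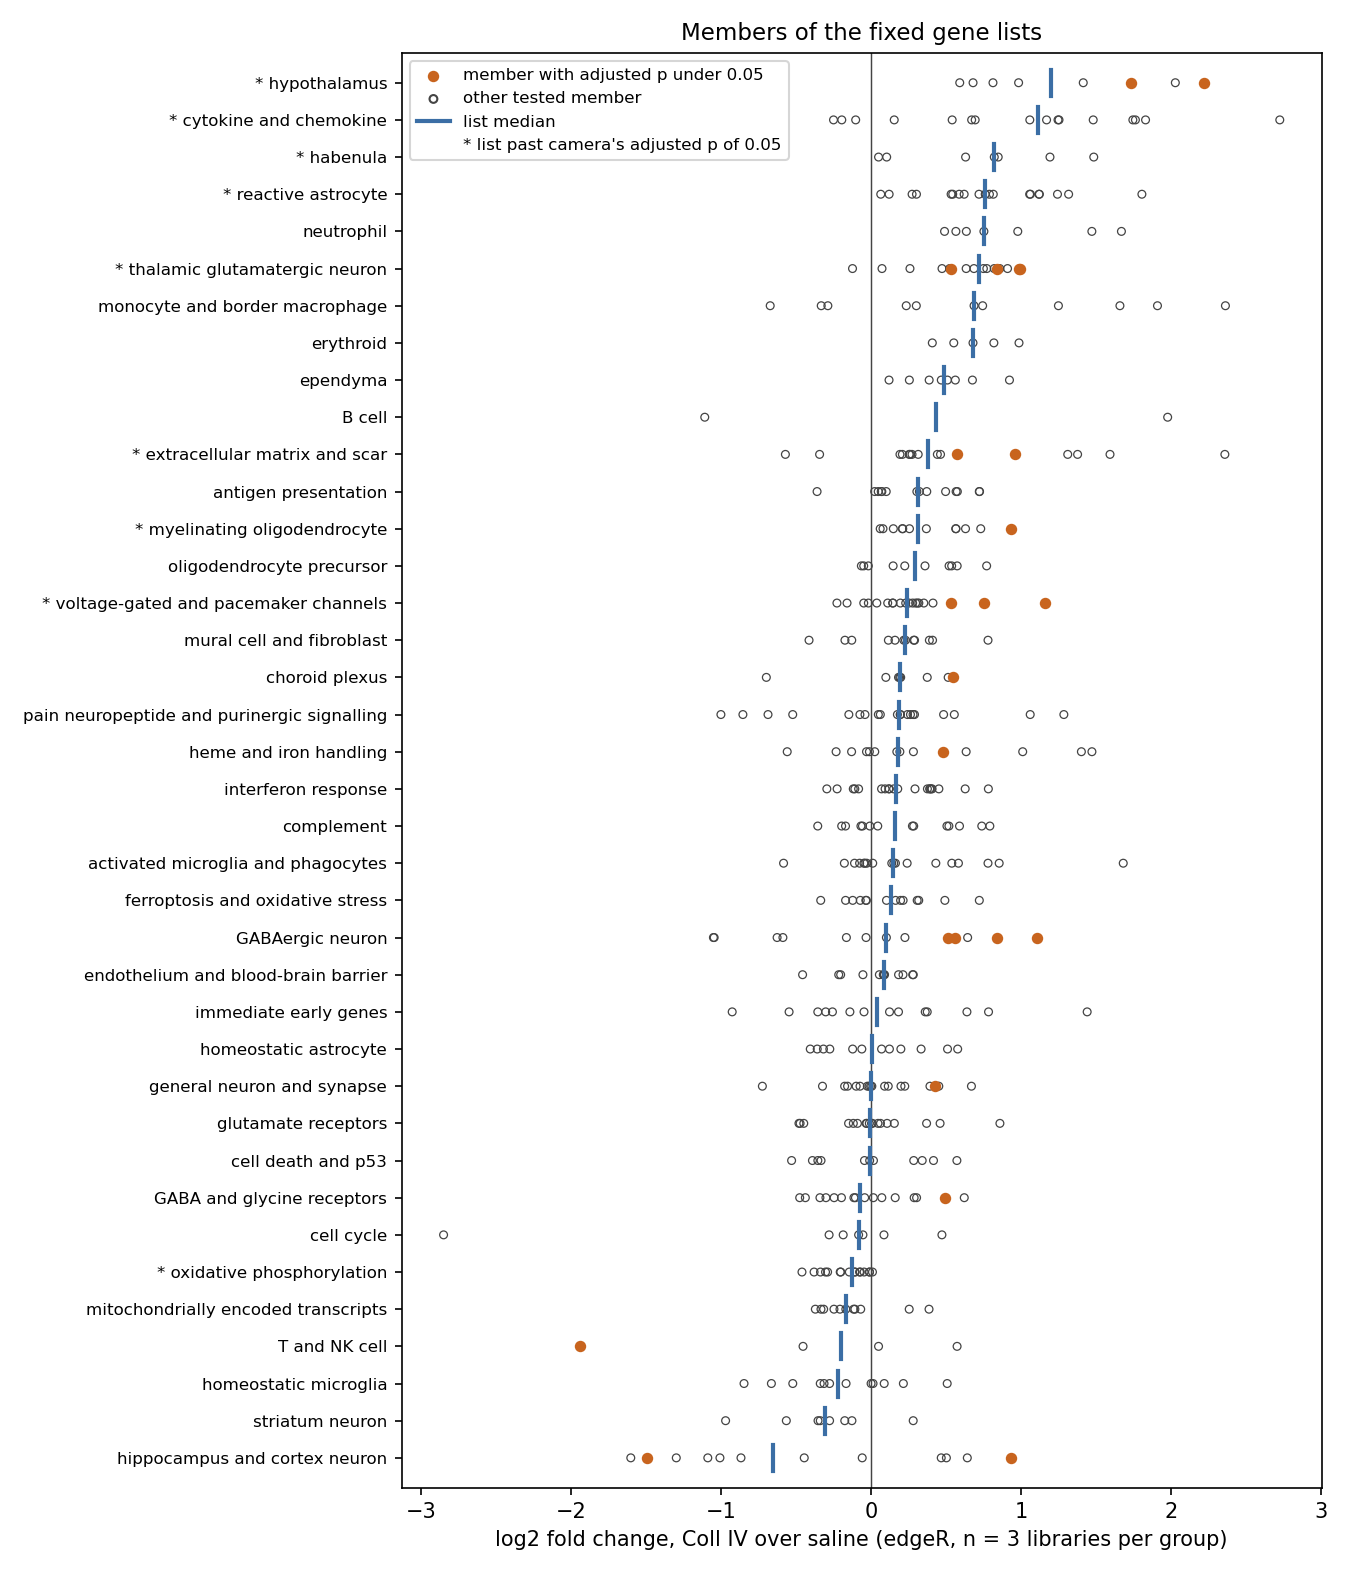
Log2 fold changes (Coll IV over saline, edgeR, n = 3 libraries per group) of the members of the 38 tested gene lists, with 1 point per gene, filled where the gene passed the test, a bar at the list's median and an asterisk for the 9 lists past camera's adjusted p of 0.05. The list medians run from -0.66 for hippocampus and cortex to 1.20 for the hypothalamus.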

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

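The tests of the length and GC correction, of the counts without ribosomal RNA-like genes and of camera with the replicate block were chosen after the results were seen. The 192 genes higher and 127 lower in Coll IV became 419 and 381 with DESeq2, which called 310 of the 319, 1191 and 57 without composition factors (225 of the 319), and 817 and 694 with no filter on low counts. With the replicate block they were 406 and 329, with the block and the length and GC correction 322 and 343, and with that correction alone 127 and 124. The causes were not tested. At an absolute log2 fold change of at least 1 the counts were 35 and 30, since this threshold takes fewer genes. At that change and an unadjusted p under 0.05, 264 were higher and 202 lower. No genes, 0 and 0, were called by glmTreat against a log2 fold change of 0.5 in edgeR (683 genes at an unadjusted p under 0.05) and by limma on the FPKM values with pseudocounts of 1 and 0.1 and with no filter, with 3074, 3056 and 3533 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.106, 0.134 and 0.254 by limma with Benjamini-Hochberg adjustment. With each library left out in turn, 0 to 166 genes rose and 0 to 100 fell in edgeR, with fewer samples in each fit. Median-ratio factors (191 and 129), the filter at 1 CPM (181 and 113), limma-voom (168 and 130) and the omission of ribosomal RNA-like genes (194 and 124) stayed within 1.5 times. Of the 47 named genes that rose or fell, all 47 lost their calls without saline replicate 1 or 3, 33 without saline replicate 2, and 22, 10 and 14 without Coll IV replicates 1, 2 and 3.

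The 9 lists past camera's adjusted p were 8 to 14 with a library left out, 13 with the replicate block, and 0 with an estimated correlation, with fry and with fry and the replicate block. No called gene (607 comparisons) named in the text turned its direction under an alternative. The groups of every called gene did not overlap, so leaving out a library could hardly turn it, and this is no separate support. No called list (126 comparisons) turned the direction of its test, which is relative to all other genes for camera but not for fry. Without composition factors 46 named genes that had not passed did so, and 35 with DESeq2. The replicate block changed calls of list genes, of which those named are given with their lists, and Sim1, Hdc and Emx1 passed with it (edgeR adjusted p = 0.0436, 0.0343 and 0.0363). Depth limited low genes such as Cd3e, Cd3d and Cd3g, which had too few counts to test.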

Other observations

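The fit without saline replicate 3 was planned, and its use against the library with most ribosomal RNA reads was decided after the results were seen, as was the length and GC correction. The 2 further region lists were written after the first tables were seen but before the values of their genes were looked at, except for Gal, which the pain neuropeptide list also holds, and their values without Gal, without the filter or without a library were computed after that.

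Coll IV replicate 2 held the extreme value of most genes that changed. Of the 192 genes that rose, 130 were highest in it, 50 in Coll IV replicate 3 and 12 in Coll IV replicate 1, and of the 127 that fell, 100, 23 and 4 were lowest in these libraries. Genes that rose had more annotated exon sequence (all exons merged), with a median of 7166 bases against 4748 for those that fell. The median of all tested protein-coding genes was 4507. In 5 length classes of protein-coding genes, from the shortest to the longest, 13, 15, 29, 41 and 84 rose and 22, 23, 20, 25 and 24 fell. The predicted gene Gm10800 was at 14145 CPM of the total counts in saline replicate 2 and 93.3 to 1366 in the other libraries.

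The thalamus, hypothalamus and habenula lists were higher in Coll IV by camera with the preset correlation (adjusted p = 0.652 for each with an estimated correlation), and several cortex genes had lower values, although the hippocampus and cortex list did not pass (camera adjusted p = 0.266) and its hippocampal genes Prox1, C1ql2, Fibcd1 and Wfs1 had log2 fold changes of 0.93, 0.64, 0.50 and 0.47. In 2 further lists of region genes, 9 of 9 tested hypothalamus genes among 20 listed were higher (median 1.26, camera p = 3.30e-07, p = 0.0547 with an estimated correlation). Sim1, Hdc and Foxb1 had 1.26, 1.15 and 1.21. The hypothalamus median was 1.24 without Gal. It was 1.25, with 16 of all 20 higher, without the filter on low counts, which some genes passed through the Coll IV libraries alone. With an estimated correlation camera's p for this list was 0.0441 without Gal and 0.0440 without the filter. It was 0.0661 with the filter at 1 CPM and 0.0783 without Coll IV replicate 2. In the other list 16 of 18 telencephalon genes were lower (median -0.73, camera p = 2.67e-06, p = 0.186 with an estimated correlation), with Stx1a at -1.22, Emx1 at -1.20 and Dkk3 at -1.06. These values are consistent with tissue pieces that held more hypothalamus and less cortex in the Coll IV samples, which is a hypothesis, and 16 of the 18 telencephalon genes were lowest in Coll IV replicate 2, without which their median was -0.49 (camera p = 6.26e-06, p = 0.104 with an estimated correlation). The library with most ribosomal RNA reads is argued against as the source, since without it the thalamus and hypothalamus medians stayed at least 0.71 above that of all genes (camera adjusted p = 4.84e-06 and 2.69e-06). A length and GC trend is argued against only as far as the correction removed it, since the lower of the 2 medians was then 0.69 (0.70 with the replicate block as well). Across protein-coding genes the rank correlation of log2 fold change with length was 0.099 before the correction and 0.053 after it. The part of the length trend that stayed is therefore not excluded. A response of thalamic neurons to the treatment stays open, as the design offers no sample that separates it from the tissue borders.

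Reactive astrocyte genes were higher in Coll IV as a list by camera with the preset correlation, though none of the 19 passed in edgeR and the call was lost with an estimated correlation (camera adjusted p = 0.799) and by fry (adjusted p = 0.414). With the preset correlation the list did not rest on Coll IV replicate 2 alone, since its median was 0.46 without that library (camera adjusted p = 0.0216). A length and GC trend, as far as the correction removed it, is argued against by a median of 0.71 after the correction, and of 0.72 with the replicate block as well (camera adjusted p = 5.29e-08). The part of the length and GC trends that the correction left was not tested. A response of astrocytes to the treatment stays open, as does a different mix of tissue, which was not tested for this list.

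Oxidative phosphorylation genes were lower in Coll IV as a list by camera with the preset correlation, a call that was lost with an estimated correlation (camera adjusted p = 0.725) and by fry (adjusted p = 0.0933). A length and GC trend, as far as the correction removed it, is argued against, since the median was then -0.17 (camera adjusted p = 0.0125 with the replicate block as well). What the correction left of the length and GC trends was not tested here either. The library with most ribosomal RNA reads is argued against as the source, since without it the list's median differed from that of all genes by -0.13 (camera adjusted p = 0.00813). The call also ended without composition factors (camera adjusted p = 0.177), where the list's median was 0.12 against 0.25 for all genes, and as that setting shifts all genes alike it says nothing for or against a cause. A lower share of mitochondria-rich cells or a response to the treatment stays open and untested.

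The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 319 genes past the threshold in edgeR, the highest of the other splits gave 0, and 1 of the 10 splits, the real one, gave as many, but with 10 splits no share under 0.1 can be had. Among the splits that part all 3 same-numbered pairs, the real one gave 735 genes with the replicate block and the others 0. These splits are fewer than 10, so the smallest share they allow is above 0.1. In every split but the real one, saline and Coll IV libraries share a side. Any difference between the groups then adds to the spread and lowers the count. The contrast with 0 therefore cannot show how many genes would pass by chance, with or without the block, and no conclusion is drawn from it.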
